A study of Mus musculus with 6 samples.

How the data were processed

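RNA was measured in Achilles tendon tissue of 6 mouse libraries, 3 labelled as sham and 3 labelled as Achilles tendon amputation, called cut tendon here. RNA was isolated with the mirVana kit and libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Gold, per the labels' protocols. That kit keeps the strand of the RNA and removes ribosomal RNA. Reads were trimmed with Trimmomatic and aligned with HISAT2 to GRCm38.p6, per the submitters' processing notes, which give no versions. The program that counted the reads and its strand setting were not given in the sources used here, so reads of genes that overlap on opposite strands may not be told apart. The deposited count table held whole read counts per gene, not normalized, with a column per library. The deposited FPKM table held the same counts divided by gene length and by library total, which was checked from the values: the implied gene length was a whole number, within 0.01 bases, for 100% of genes with counts in all 6 libraries.

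The tables held 21878 genes, of which 4031 had no count in any library. Positions were taken from a GRCm38.p6 annotation by NCBI gene identifier for 21727 genes, and 151 had no match. Library totals ran from 23916839 to 31346730 counts, so that a single count was 0.0319 to 0.0418 CPM. Pairs of libraries were compared for duplication, and the closest pair, sham 1 and 2, still differed by a chi-square of 15.6 per gene. Groups and replicate numbers were read from the labels, which give neither the time after surgery nor the animals' identity. The comparison, the tests, the gene lists, the rule for named genes and all alternatives except the muscle covariate were chosen before the data were examined.

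Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14561 tested and 7317 not tested, and libraries were scaled by TMM. Cut tendon was compared with sham by edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p under 0.05. The common biological coefficient of variation was 0.296. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM are TMM-normalized and given as mean ± SD over 3 libraries, and log2 fold changes as value ± SE. A set of 28 gene lists was written from general knowledge of the tissue and of the subjects in the series title. For each list the members called were counted over all genes and adjusted over the list alone. The list as a whole was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over the 27 lists with tested genes. The same test was run with an estimated correlation. The lymphocyte list had 16 of 21 members in the tables, skin 19 of 20, erythroid 14 of 15 and the mitochondrial genome 0 of 13, so the last is not analysed here. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1.

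Genes named by rule were Klf2, Pparg, and the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among those called, with a mean of at least 5 CPM, no overlap between groups and no model name. Of each list, the 2 members with the smallest p were named, and the member with the smallest p in the other direction where members were called both ways. Tnmd, Scx, Col1a1, Ttn, Sox9, Sp7, Adipoq, Trem2, Bmp2, Inhba, Ptgs2, Hist1h1b, Ctsh, Chsy1, Mgat2 and Bckdhb were chosen after their values were seen. Cox6a1, Cox6a2, Cox7a1, Cox7a2, Cox8a, Cox8b, Slc25a4 and Slc25a5 were added for a test of isoforms after the muscle shares of the libraries were seen. Of 104 genes selected in these ways, 2 are not reported here, and 22 share exon sequence with another annotated gene, 2 of them (Sbsn and Top2a) on the same strand and 20, among them Runx2, Il1b, Myoc, Nos3, Timp4, Matn4 and Col9a3, on the other strand, so their values are uncertain to that extent. Lect1 was not found in the annotation used for this check.

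The fit was tested on simulated data of 14561 genes, in which 100 genes were changed 4-fold and 100 were changed 2-fold. Of these, 79% and 12% were called, and 6 unchanged genes were called, 6.19% of all calls. All 4 lists set to move were called by camera, and 0 of the other lists. Simulated genes were drawn independently of each other, so this does not show how camera with its preset correlation behaves where genes are correlated. The shares recovered also hold only for 200 changed genes, far fewer than were called in the data. The changed genes were drawn only from those above a floor of mean CPM, so the shares do not hold for genes of lower abundance. No library was simulated to stand apart from its group.

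Alternatives were DESeq2 1.42.0 size factors or upper quartile scaling in edgeR, DESeq2's Wald test, limma-voom, no filter, a filter of at least 10 counts in all 3 libraries of a group, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Others were library sizes without muscle and erythroid genes, a change of at least 2-fold, the replicate number as a block, and each library left out in turn. The log2 CPM of the skeletal muscle list per library was added as a covariate, chosen after seeing the data. Within the groups the muscle share varied mostly in cut tendon (1.63%, 0.531% and 15.8%, against 19.1% to 21.2% in sham). Values adjusted for it therefore rest largely on cut 3 against sham, and are no check separate from the medians of cut 3. No scaling moved the median of all genes by more than 0.1 log2 units. Deviations from the group means were correlated between same-numbered libraries (0.26, 0.13 and 0.41 for numbers 1 to 3), all above 0.1, so the numbers were taken to pair the samples. That pairing comes from the data only, the labels name none, and sham 1 correlated with cut 2 at 0.24 and sham 2 with cut 1 at 0.11. The threshold thus did not separate same-numbered from other pairs, and all results with the replicate block carry this doubt. A single count table was used, and no column was left out.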

Results

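RNA was sequenced from Achilles tendon tissue of mice after a sham operation or after the tendon had been cut, with 3 libraries per group. The series title sets the comparison in a study of the transcription factors KLF2 and PPARγ and of mitochondrial dysfunction in heterotopic ossification, the formation of bone outside the skeleton after injury. The libraries are called sham 1 to 3 and cut 1 to 3 after the numbers in their labels. They held 23916839, 26176650 and 27140226 counts in the sham group and 28410231, 30715022 and 31346730 in the cut-tendon group (n = 3 each; exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). A single count stood for 0.0319 to 0.0418 CPM (counts scaled by library size), and 16345 to 16578 genes had at least 1 count in a library. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

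Skeletal muscle and collagen transcripts set the libraries apart. The 30 genes of the skeletal muscle list, which code for the contractile apparatus and related muscle proteins, took 19.6%, 19.1% and 21.2% of the counts in sham 1 to 3, and 1.63%, 0.531% and 15.8% in cut 1 to 3. Ttn, the giant spring protein of the muscle sarcomere, alone took 9.57% to 10.6% of the sham counts, 0.621% of cut 1, 0.199% of cut 2 and 5.01% of cut 3. Col1a1, a chain of type I collagen, took 0.562%, 0.492% and 0.207% in sham 1 to 3 and 7.05%, 8.68% and 3.28% in cut 1 to 3. The first principal component of log2 CPM held 80.4% of the variance and placed the sham libraries at -60.7, -64.5 and -76.7, cut 1 and 2 at 81.6 and 111, and cut 3 between them at 9.57. Cut 3 thus carried a muscle share near that of the sham libraries.

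**Figure D1:**
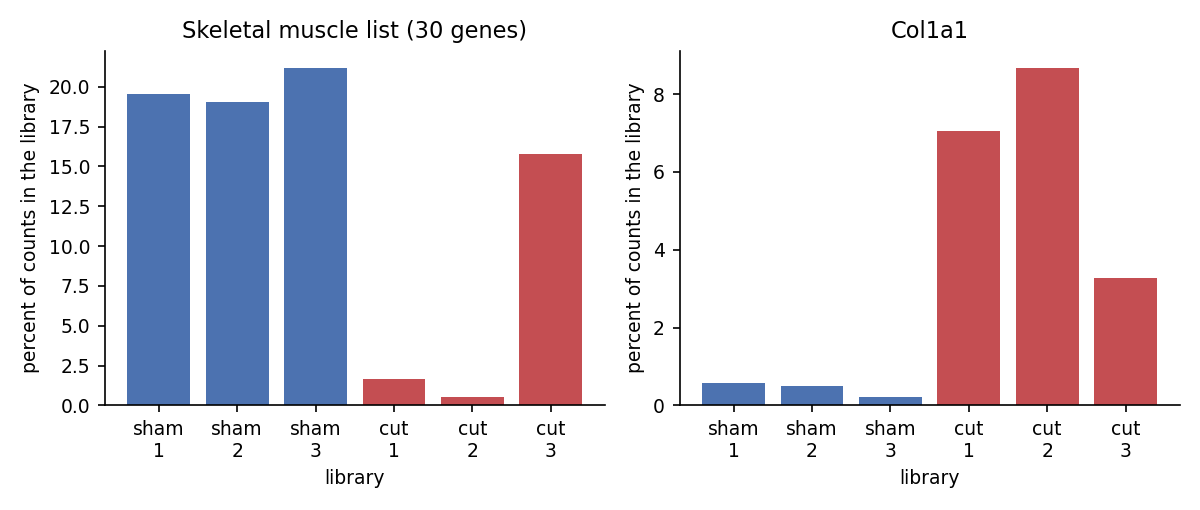
Bars show the percent of each library's counts taken by the 30 genes of the skeletal muscle list (left) and by Col1a1 (right), for 3 sham (blue) and 3 cut-tendon (red) libraries. The muscle share was 19.1% to 21.2% in sham libraries, 1.63% and 0.531% in cut 1 and 2, and 15.8% in cut 3, while Col1a1 was at 0.207% to 0.562% in sham and 3.28% to 8.68% in cut tendon.

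The comparison of cut with sham tendon asked which genes differed after the injury. Tnn, Mmp13 and Col2a1 had the largest increases under the naming rule, and Coch the largest decrease. Tnn (tenascin-N, an extracellular matrix glycoprotein) rose by log2 9.84 ± 0.80 (SE, n = 3 per group), from 0.513 ± 0.28 to 473 ± 292 CPM (SD). The collagenase gene Mmp13 rose by 9.70 ± 0.95, from 1.90 ± 0.646 to 1585 ± 1110 CPM. Col2a1, the type II collagen of cartilage, rose by 8.70 ± 1.13, from 9.65 ± 6.76 to 4019 ± 2734 CPM. C1qtnf3 (7.79 ± 0.44), Cthrc1 (7.77 ± 0.50), Lrrc15 (7.15 ± 0.53), the 3 type IX collagen genes Col9a2 (7.62 ± 0.88), Col9a1 (7.18 ± 0.97) and Col9a3 (7.11 ± 0.89), and Lect1, which codes for chondromodulin (6.92 ± 0.95; not called by limma-voom, at 6.38), completed the 10 highest under the naming rule. The 10 lowest were led by Coch, an extracellular matrix protein first known from the inner ear, which fell by 6.44 ± 0.86 on the log2 scale, from 53.4 ± 38.8 to 0.613 ± 0.414 CPM. Stk32a (-4.11 ± 0.66), Myoc (myocilin, -3.89 ± 0.47), the metalloproteinase inhibitor Timp4 (-3.86 ± 0.66), the adipocyte hormone gene Lep (-3.85 ± 0.76), Lrrc52 (-3.83 ± 0.85), the calcium channel gene Cacna1e (-3.81 ± 0.29), Nnat (-3.76 ± 0.62), the natriuretic peptide clearance receptor Npr3 (-3.67 ± 0.65) and Ppara (-3.29 ± 0.91), a nuclear receptor that drives fatty acid oxidation, followed. Adjusted p-values of these 20 genes lay between 0.00238 and 0.0362 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups did not overlap for any of them, a condition of the rule that chance alone meets in 10% of genes with 3 against 3 libraries. In these data 54.8% of all tested genes met it. Lep (-3.46) and Nnat (-3.22) were not called with the log2 CPM of the muscle list as a covariate. Lrrc52 was not called without sham 2, sham 3 or cut 1 (log2 -3.92, -3.52 and -3.40), nor Ppara without sham 1, sham 2, sham 3 or cut 1 (-3.46, -3.31, -3.12 and -2.96). Both kept their calls with the muscle covariate.

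In GRCm38.p6 coordinates, Tnn lies on chromosome 1 at 160085029 to 160153692, Mmp13 on chromosome 9 at 7272514 to 7283333, Col2a1 on chromosome 15 at 97975602 to 98004724, and Coch on chromosome 12 at 51593283 to 51606619. Of 14561 genes tested, 2968 were higher and 1789 lower in cut tendon at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group), and 9804 were not called. A change of at least 2-fold was seen in 1813 of the higher and 1006 of the lower genes. The median log2 fold change over all tested genes was -0.02. The counts depended on every library: without sham 1, 2 and 3 they were 1566 higher and 670 lower, 1091 and 436, and 1359 and 798, and without cut 1, 2 and 3 they were 1585 and 688, 1863 and 893, and 4212 and 4392. With the log2 CPM of the skeletal muscle list as a covariate, an alternative chosen after seeing the data, 1483 genes were higher and 633 lower, and DESeq2 called 2776 lower.

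Klf2 and Pparg, the genes named in the series title, changed in opposite directions. Klf2 (NCBI gene 16598, chromosome 8, 72319062 to 72321654), a flow-responsive transcription factor of endothelium and immune cells, rose by log2 0.89 ± 0.27, a 1.86-fold change, from 58.0 ± 9.59 to 108 ± 35.8 CPM. Pparg (NCBI gene 19016, chromosome 6, 115360879 to 115490404), the nuclear receptor that governs adipocyte differentiation, fell by 1.70 ± 0.15 on the log2 scale, from 33.9 ± 2.82 to 10.4 ± 1.54 CPM. The adjusted p was 0.0469 for Klf2 and 0.00318 for Pparg (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group). Klf2 stood at 106, 144 and 72.3 CPM in cut 1 to 3, lowest in cut 3, the cut-tendon library with the high muscle share. Pparg stood at 11.9, 8.84 and 10.5 CPM. Klf2 was not called without sham 1 (log2 0.99), sham 2 (0.90), sham 3 (0.73), cut 1 (0.90) or cut 2 (0.63), with no filter on low counts (0.87), on FPKM (0.83 and 0.85), with muscle and erythroid genes out of the library sizes (0.86) or with the muscle covariate (0.22), so its call rested near the threshold. Pparg was called under each of these settings, with log2 values between -1.81 and -1.43 and adjusted p-values of at most 0.0286.

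**Figure D2:**
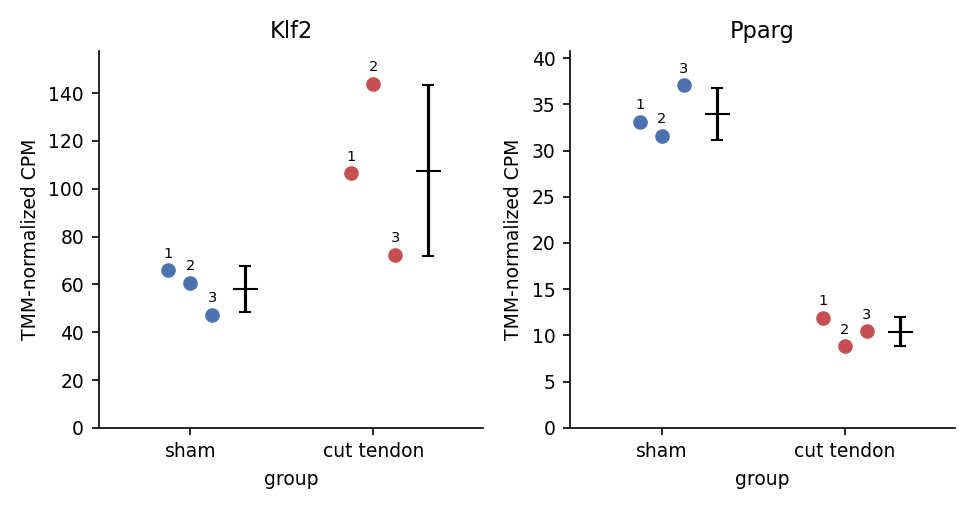
Points show the TMM-normalized CPM of Klf2 (left) and Pparg (right) in each library, numbered by replicate, for sham (blue) and cut tendon (red), and black bars show the mean and SD (n = 3). Klf2 lay at 47.3 to 65.9 CPM in sham and 72.3 to 144 in cut tendon, and Pparg at 31.6 to 37.1 in sham and 8.84 to 11.9 in cut tendon.

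Most adipocyte genes were lower. Of 25 tested members of the PPARG and adipocyte list, 20 were lower and 5 were not called (22 lower adjusted over the list alone). Plin1, which coats lipid droplets, fell by 2.35 ± 0.31 on the log2 scale, from 141 ± 23 to 27.7 ± 10.1 CPM, and Dgat2, an enzyme of triglyceride synthesis, fell by 2.58 ± 0.36. Adipoq, the adipocyte hormone adiponectin, fell by 1.99 ± 0.31 (adjusted p = 0.00714, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median log2 fold change of the list was -1.94 (limma camera, adjusted p = 6.2e-09; adjusted p = 0.538 with an estimated correlation), and its per-library medians against the sham mean were -1.92, -2.93 and -1.33 in cut 1 to 3. With sham 1 to 3 and cut 1 to 3 left out in turn, 13, 10, 11, 12, 17 and 23 members were lower, and 13 with the muscle covariate.

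Of the 23 fatty acid oxidation genes, 17 were lower, 1 was higher and 5 were not called (20 lower and 1 higher adjusted over the list alone). Etfa, an electron transfer flavoprotein subunit, fell by 1.28 ± 0.30, from 132 ± 13.9 to 54.4 ± 23.1 CPM. The member that rose was Cpt1a, the carnitine palmitoyltransferase form of liver and many other tissues, by log2 0.69 ± 0.12, from 42.4 ± 1.54 to 68.3 ± 5.9 CPM. The list median was -1.66 (limma camera, adjusted p = 2.4e-06; adjusted p = 0.612 with an estimated correlation). This list moved in part with the muscle share. Its medians were -2.23 and -2.33 in cut 1 and 2, with 1.63% and 0.531% of counts from muscle genes. In cut 3, with 15.8%, it stood at -0.80, while the muscle list stood at -0.10. When sham 1 to 3 and cut 1 to 3 were left out in turn, 0, 0, 0, 0, 2 and 22 members were lower, and 9 were lower with the muscle covariate. Camera with its preset correlation still called the list lower with the muscle covariate. Etfa was called only with all 6 libraries or without cut 3 (log2 -1.36 to -1.11 without each of the others), and Cpt1a was not called without sham 2 (0.68).

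Mitochondrial genes had lower values in cut 1 and 2 and near-sham values in cut 3. Of the 76 nuclear genes of oxidative phosphorylation (OXPHOS), 74 had a negative log2 fold change (median -1.02) and none was called, over all genes or adjusted over the list alone, in edgeR's quasi-likelihood test. In that test 19 had an unadjusted p under 0.05, while DESeq2 called 31 lower, limma-voom 6 and limma on log2(FPKM + 1) 22. The complex I genes Ndufa11 and Ndufb10 stood at log2 -1.09 ± 0.36 and -1.16 ± 0.39, with adjusted p-values of 0.0595 and 0.061 in edgeR's test with Benjamini-Hochberg adjustment, and each was called with the replicate number as a block (-1.20 and -1.29). The 18 genes of the tricarboxylic acid (TCA) cycle, all negative with a median of -1.19, likewise held no call (none adjusted over the list alone; 9 at an unadjusted p under 0.05, 12 in DESeq2, 4 in limma-voom). Suclg2 and Dlst, which code for subunits of TCA cycle enzymes, stood at -0.997 ± 0.318 and -1.04 ± 0.36, and were called with the block (-1.08 and -1.16). limma camera placed both lists lower, with adjusted p = 4.6e-09 for OXPHOS and 9.1e-05 for the TCA cycle (adjusted p = 0.612 with an estimated correlation for each). The per-library OXPHOS medians were -1.86, -1.80 and -0.13 and those of the TCA cycle -1.97, -2.10 and -0.28, beside muscle shares of 1.63%, 0.531% and 15.8% in cut 1 to 3. Without cut 3, 74 OXPHOS and 18 TCA cycle genes were lower, with the replicate block 44 and 14, and with the muscle covariate none, at medians of -0.14 and -0.26. These covariate medians lay near those of cut 3 (-0.13 and -0.28), on which the adjustment largely rests. The 13 genes of the mitochondrial genome were not measured in the tables used here, with 0 of 13 present.

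In the list of mitochondrial dynamics and biogenesis, 5 of 32 genes were lower and 27 were not called (none adjusted over the list alone in edgeR's test, where 11 had an unadjusted p under 0.05; DESeq2 called 15 lower and limma-voom 10). Ppargc1a, the coactivator PGC-1α that promotes mitochondrial biogenesis, fell by 3.11 ± 0.70, from 117 ± 31.3 to 13.5 ± 12.6 CPM, and Polrmt, the mitochondrial RNA polymerase, by 0.83 ± 0.16, from 26.1 ± 2.03 to 14.7 ± 2.83 CPM. The median was -0.70 (limma camera, adjusted p = 4.3e-05; adjusted p = 0.612 with an estimated correlation). The per-library medians of -1.10, -1.11 and -0.21 again followed the muscle share of cut 1 to 3. Without sham 1 to 3 and cut 1 to 3 in turn, 2, 0, 0, 0, 2 and 26 members were lower, 15 were lower with the replicate block, 8 with upper quartile scaling or DESeq2 size factors and 1 with the muscle covariate. Ppargc1a and Polrmt were not called without sham 2 (log2 -2.95 and -0.88), sham 3 (-3.09 and -0.80) or cut 1 (-2.87 and -0.75). With the muscle covariate Ppargc1a kept its call and Polrmt did not. In cut 3 Ppargc1a stood at 27.8 CPM, against 82.3 to 143 in sham.

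The skeletal muscle list itself was not called gene by gene, because cut 3 lay close to the sham libraries. All 30 genes had a negative log2 fold change (median -1.55; limma camera, adjusted p = 2.8e-05; adjusted p = 0.612 with an estimated correlation), and the per-library medians were -3.47, -4.72 and -0.10. No gene passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone. In that test 3 had an unadjusted p under 0.05, limma-voom called none, and DESeq2 called 9 of the 18 to which it gave an adjusted p. Ttn stood at log2 -2.30 ± 1.75, the regulatory myosin light chain Myl2 at -2.37 ± 0.90 and myoglobin (Mb), which stores oxygen in muscle, at -2.43 ± 0.95. Myl2 and Mb were called with the replicate block (-3.21 and -3.27), as were 5 members in all, and 30 of 30 were lower without cut 3. Of 12 muscle regeneration genes, none was called in edgeR's test over all genes or adjusted over the list alone, none had an unadjusted p under 0.05, and DESeq2 and limma-voom called none (median -0.37; limma camera, adjusted p = 0.243). Ncam1 stood at 0.36 ± 0.22 and the satellite cell cadherin Cdh15 at -1.35 ± 0.97. Per-library medians were -1.94, -2.89 and 0.41. Without cut 3, 10 members were lower and limma camera called the list lower (-2.71, adjusted p = 0.00163), and with the muscle covariate 3 were higher and camera called it higher (0.71, adjusted p = 0.0173).

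**Figure D3:**
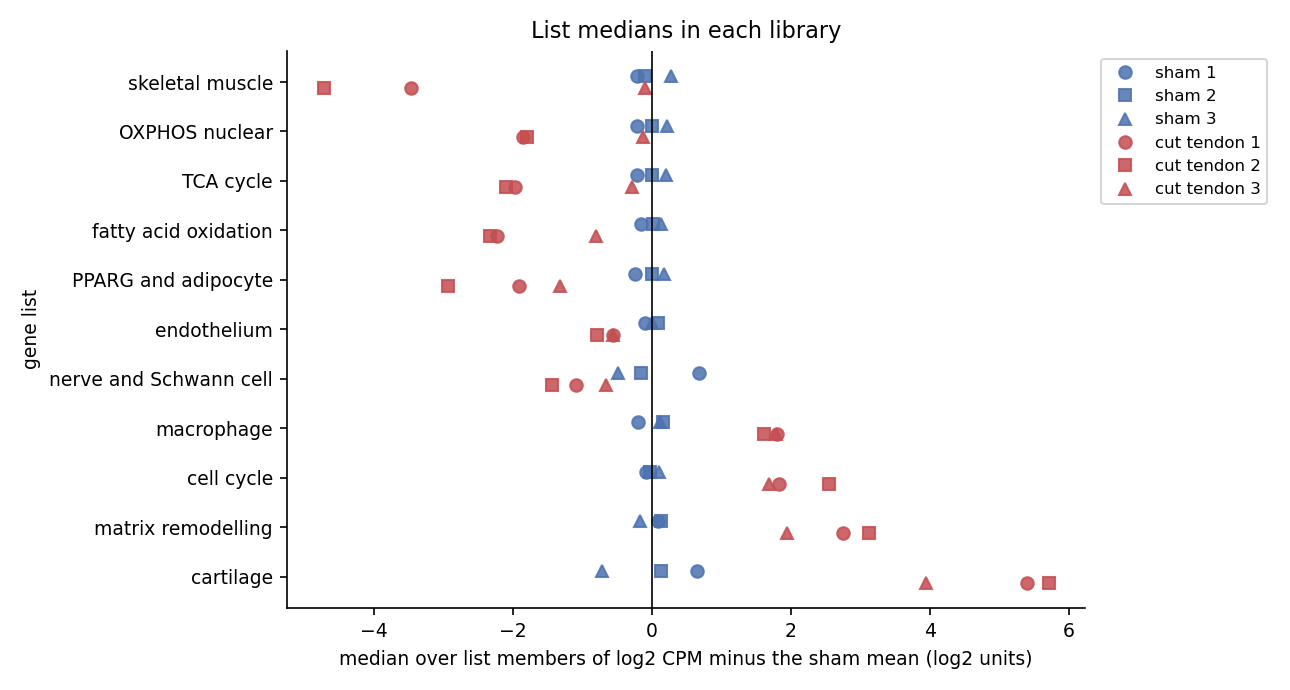
Points show, for 11 gene lists, the median over list members of log2 CPM minus the sham mean (horizontal axis, log2 units), with 3 sham (blue) and 3 cut-tendon (red) libraries marked by replicate. Cut 3 lay near the sham libraries for skeletal muscle (-0.10) and OXPHOS (-0.13), apart from cut 1 (-3.47 and -1.86) and cut 2 (-4.72 and -1.80), but with them for macrophage (1.79, against 1.81 and 1.61).

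Most cartilage genes were higher. In the cartilage list 16 of 22 tested genes were higher, 1 was lower and 5 were not called (16 higher and 2 lower adjusted over the list alone). Acan, the large proteoglycan aggrecan, rose by log2 6.81 ± 0.74, from 17.7 ± 9.11 to 1979 ± 1093 CPM, and Matn4, a matrix adaptor protein, by 5.60 ± 0.50, from 6.94 ± 3.5 to 336 ± 94.9 CPM. Sox9, the transcription factor that sets the chondrocyte fate, rose by 1.69 ± 0.31 (not called without sham 2, at 1.64). The member that fell was Cytl1, a secreted cytokine-like protein, by 2.50 ± 0.36. The list median was 5.34 (limma camera, adjusted p = 1.8e-05; adjusted p = 0.612 with an estimated correlation), and the per-library medians were 5.40, 5.71 and 3.94 in cut 1 to 3, lowest in cut 3, which had the larger muscle share. With the replicate block 3 members were lower.

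In the bone list 8 of 20 tested genes were higher and 12 were not called (8 higher adjusted over the list alone). Runx2, the transcription factor that commits cells to the osteoblast lineage, rose by 2.03 ± 0.29, from 6.06 ± 1.53 to 24.8 ± 7.54 CPM. Tnfsf11, the osteoclast-inducing cytokine RANKL, rose by 3.38 ± 0.69 at low abundance, from 0.221 ± 0.136 to 2.34 ± 1.32 CPM, and was not called without sham 1 (3.45) or sham 2 (2.95). Sp7, a transcription factor of later osteoblasts, stood at 1.93 ± 0.85 and was not called (adjusted p = 0.121 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 0.414 ± 0.421 and 1.57 ± 1.05 CPM, although without cut 3 it was (2.37). The list as a whole was not called (median 1.10; limma camera, adjusted p = 0.074), except without sham 1 (1.40) or cut 3 (1.48). With sham 1 to 3 and cut 1 to 3 left out in turn, 2, 1, 2, 2, 4 and 11 bone genes were higher, and 4 with the muscle covariate, where the list median was -0.00693. The per-library medians were 1.14, 1.64 and 0.11, the last in the library with 15.8% muscle counts.

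Of 12 osteoclast genes, 6 were higher and 6 were not called (8 higher and 1 lower adjusted over the list alone). Ctsk, the collagen-degrading protease of osteoclasts, rose by log2 3.75 ± 0.34, from 43.2 ± 8.96 to 582 ± 188 CPM, and Atp6v0d2, a proton pump subunit enriched in osteoclasts, by 4.36 ± 0.53. The median was 0.71 (limma camera, adjusted p = 0.0176; adjusted p = 0.369 with an estimated correlation). When sham 1 to 3 and cut 1 to 3 were left out in turn, 3, 2, 3, 3, 5 and 10 members were higher, and 2 with the muscle covariate, where the list was not called (0.43). The per-library medians were 0.90, 0.94 and 0.45, lowest in cut 3, the cut-tendon library with the high muscle share.

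Most matrix genes were higher. Of 36 matrix remodelling genes, 31 were higher, 1 was lower and 4 were not called (31 higher and 3 lower adjusted over the list alone). Postn (periostin), a matricellular protein of healing connective tissue, rose by log2 4.93 ± 0.32, from 72.3 ± 8 to 2210 ± 384 CPM, and the metalloproteinase gene Mmp3 by 4.48 ± 0.24, from 6.20 ± 0.879 to 139 ± 32.7 CPM; the member that fell was Timp4. The list median was 2.62 (limma camera, adjusted p = 3.4e-11; adjusted p = 0.538 with an estimated correlation), with 2.75, 3.13 and 1.95 in cut 1 to 3. Of 24 tendon genes, 13 were higher and 11 were not called (14 higher and 1 lower adjusted over the list alone; median 1.76; limma camera, adjusted p = 3.0e-05; adjusted p = 0.612 with an estimated correlation). The collagen-binding proteoglycan Lum rose by 4.81 ± 0.46, Col14a1 by 3.01 ± 0.33 and the tenocyte marker Tnmd by 3.42 ± 0.40, from 64.1 ± 17.5 to 685 ± 292 CPM. Scx, a transcription factor of tendon cells, rose by 1.78 ± 0.47 with all 6 libraries, but with a library left out was called only without cut 3 (log2 1.18 to 2.08 without each of the others). Without sham 1 to 3 and cut 1 to 3 in turn, 8, 6, 8, 9, 9 and 17 tendon genes were higher, and the per-library medians were 1.67, 2.39 and 1.16, lowest in cut 3 with its muscle share of 15.8%. With the muscle covariate the list median was 0.85, and Scx (0.71) was not called.

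Col1a1, a member of both the bone and the tendon list, rose by 3.92 ± 1.22, from 4174 ± 1779 to 63020 ± 27752 CPM. Its adjusted p was 0.04998 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was not called with the replicate block (3.92, adjusted p = 0.0583 in edgeR's test), under the filter of 10 counts (3.91), with muscle and erythroid genes out of the library sizes (3.88), or without sham 1 (4.16), sham 2 (4.02), sham 3 (3.57), cut 1 (3.90) or cut 2 (3.58). Its lowest value among the cut-tendon libraries was in cut 3, the library with a muscle share of 15.8%.

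Genes of BMP and TGF-beta signalling, the pathways that direct cartilage and bone formation, went both ways. Of 42 genes, 9 were higher, 11 were lower and 22 were not called (11 higher and 12 lower adjusted over the list alone). Over all 14561 tested genes, 2968 were higher and 1789 lower, so the share of higher members was near that of all genes. Bmp1, a protease that matures procollagens, rose by log2 1.94 ± 0.29, and Inhba, the activin A subunit, by 2.03 ± 0.37 (not called without sham 2, at 2.01). Smad7, an inhibitor of the pathway, fell by 0.96 ± 0.10, from 40 ± 2.48 to 20.6 ± 0.578 CPM, and Inhbb, the activin B subunit, by 2.28 ± 0.25. Bmp2, a ligand that induces bone, fell by 1.67 ± 0.38, from 20.3 ± 9.07 to 6.39 ± 1.51 CPM, but was not called without sham 1 (-1.33), sham 2 (-1.65), cut 1 (-1.80) or cut 2 (-1.73). The list was not called (limma camera, adjusted p = 0.752): its median was 0.03 and its mean -0.06, and camera's direction was down. With sham 1 to 3 and cut 1 to 3 left out in turn, 3, 2, 2, 3, 5 and 14 members were higher and 4, 4, 8, 6, 6 and 12 lower, and with the muscle covariate 3 were higher and 6 lower.

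Most macrophage genes were higher. Of 25 macrophage genes, 22 were higher and 3 were not called (22 higher and 1 lower adjusted over the list alone). The lysozyme gene Lyz2 rose by log2 2.25 ± 0.19, from 95.4 ± 14.8 to 453 ± 28.8 CPM, and Cd68, a lysosomal glycoprotein of macrophages, by 2.27 ± 0.20. Trem2, a lipid-sensing receptor of macrophages, rose by 3.03 ± 0.30. The median was 1.79 (limma camera, adjusted p = 1.6e-10; adjusted p = 0.369 with an estimated correlation), and the per-library medians of 1.81, 1.61 and 1.79 did not follow the muscle share. Of 9 lymphocyte genes, 5 were higher and 4 were not called (7 higher adjusted over the list alone; median 1.45; limma camera, adjusted p = 0.000184; adjusted p = 0.369 with an estimated correlation). Cd4 rose by 3.999 ± 0.343, from 0.547 ± 0.118 to 8.80 ± 2.79 CPM, and Jchain, the joining chain of secreted antibodies, was at 0.170 ± 0.086 and 8.41 ± 3.55 CPM. Without any 1 of the sham libraries, 3 lymphocyte genes were higher.

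Of 25 inflammatory mediator genes, 11 were higher and 14 were not called (11 higher adjusted over the list alone; median 1.32; limma camera, adjusted p = 0.000645; adjusted p = 0.369 with an estimated correlation). Il1b, the interleukin-1β gene and a member of the neutrophil list too, rose by log2 3.56 ± 0.40, from 0.405 ± 0.154 to 4.81 ± 1.53 CPM. Il6 was at 0.0769 ± 0.0364 CPM in sham, near the level of a single count, and at 0.936 ± 0.265 CPM in cut tendon. Ptgs2, the inducible cyclooxygenase, rose by 3.57 ± 0.79, but was not called without sham 2 (3.39), sham 3 (3.25) or cut 1 (3.58), nor by limma-voom (3.31). When sham 1 to 3 and cut 1 to 3 were left out in turn, 7, 3, 6, 7, 8 and 14 mediators were higher, and 4 with the muscle covariate. The per-library medians were 1.30, 1.40 and 0.81, lowest in cut 3 with its muscle share of 15.8%. Of 8 neutrophil genes, 2 were higher and 6 were not called (2 higher and 1 lower adjusted over the list alone; median 0.63; limma camera, adjusted p = 0.424). They were Il1b and Csf3r, the receptor of the granulocyte growth factor, which rose by 1.64 ± 0.33 and was not called without sham 1 (1.501), sham 2 (1.46) or cut 1 (1.46), which left 1 neutrophil gene higher in each case. Without sham 1 the neutrophil median was 0.0364, and the per-library medians were 0.93, -0.21 and 1.28 in cut 1 to 3.

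Most cell cycle genes were higher. Of 35 genes, 29 were higher and 6 were not called (32 higher adjusted over the list alone). Mki67, the proliferation marker Ki-67, rose by log2 2.96 ± 0.23, from 5.80 ± 0.12 to 45.3 ± 13.2 CPM, and Top2a, the topoisomerase that untangles replicated chromosomes, by 2.96 ± 0.25, from 3.13 ± 0.491 to 24.3 ± 6.81 CPM. The list median was 2.15 (limma camera, adjusted p = 5.4e-12; adjusted p = 0.49 with an estimated correlation), and the per-library medians were 1.83, 2.55 and 1.69. Without sham 2, 19 members were higher, and 19 with the muscle covariate.

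More endothelial genes were lower than higher. Of 22 endothelial genes, 13 were lower, 1 was higher and 8 were not called (14 lower and 1 higher adjusted over the list alone). Nos3, the endothelial nitric oxide synthase, fell by 1.14 ± 0.16, from 48.7 ± 1.49 to 22.1 ± 4.17 CPM, while the ETS transcription factor Erg, which is expressed in endothelium and in cartilage, rose by log2 1.23 ± 0.17, from 30.3 ± 2.37 to 71 ± 14 CPM. The median was -0.62 (limma camera, adjusted p = 2.8e-05; adjusted p = 0.538 with an estimated correlation), with -0.55, -0.79 and -0.56 in cut 1 to 3. Without sham 1 to 3 and cut 1 to 3 in turn, 8, 6, 8, 7, 9 and 17 were lower, and 7 with the muscle covariate. Of 16 smooth muscle and pericyte genes, 4 were lower, 2 were higher and 10 were not called (4 and 2 adjusted over the list alone; median -0.51; limma camera, adjusted p = 0.0847, and called only without sham 3, at -0.62). Lmod1, a smooth muscle actin nucleator, fell by 1.53 ± 0.29 (not called without sham 2, at -1.51) and the adhesion molecule Mcam by 0.59 ± 0.13 (not called without sham 1 to 3 or cut 2, at -0.65 to -0.52). The pericyte proteoglycan Cspg4 rose by 1.82 ± 0.41 (not called without sham 2, sham 3 or cut 1, at 1.57 to 1.84). With sham 1 to 3 and cut 1 to 3 left out in turn, 1, 0, 3, 2, 2 and 9 of these genes were lower, and none with the muscle covariate. The per-library medians were -0.55, -0.72 and -0.14, nearest to sham in cut 3, where the muscle share was near sham too.

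Of 16 nerve and Schwann cell genes, 8 were lower and 8 were not called (8 lower and 1 higher adjusted over the list alone). Drp2, a dystrophin-related protein of myelinating Schwann cells, fell by 1.45 ± 0.33, from 122 ± 56.9 to 44.7 ± 7.02 CPM, and the Schwann cell cadherin Cdh19 by 1.21 ± 0.26. The median was -1.19 (limma camera, adjusted p = 0.0259; adjusted p = 0.675 with an estimated correlation), and the list was not called without sham 1 (-0.80) or cut 3 (-1.36). When sham 1 to 3 and cut 1 to 3 were left out in turn, 2, 0, 6, 0, 1 and 11 members were lower, 5 with the replicate block and none with the muscle covariate, where the list was not called (-0.73). The per-library medians were -1.10, -1.44 and -0.66 in cut 1 to 3, with muscle shares of 1.63%, 0.531% and 15.8%. Drp2 and Cdh19 were not called without sham 2 (log2 -1.60 and -1.32) or cut 1 (-1.41 and -1.26), nor Drp2 without cut 2 (-1.36).

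In the KLF family, which includes Klf2, 3 of 15 tested genes were higher, 1 was lower and 11 were not called (1 lower and none higher adjusted over the list alone in edgeR's test, where 5 higher and 2 lower had an unadjusted p under 0.05). Klf9, a target of glucocorticoid and thyroid hormones, fell by 0.83 ± 0.14, from 203 ± 16.1 to 114 ± 8.17 CPM, and Klf16 rose by log2 0.91 ± 0.25, from 7.68 ± 0.852 to 14.4 ± 4.26 CPM. The list was not called (limma camera, adjusted p = 0.645): its median was 0.22 and its mean -0.02, and camera's direction was up. No member was higher without sham 1 to 3, cut 1 or cut 2, where Klf16 stood at 0.74 to 0.997, on FPKM or with the muscle covariate. Without cut 3, 8 were higher and 3 lower, and DESeq2 also called 3 lower.

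Of 24 antioxidant genes, 5 were higher and 4 lower (5 and 4 adjusted over the list alone; median -0.22; limma camera, adjusted p = 0.214). The heme oxygenase gene Hmox1 rose by log2 1.70 ± 0.26, from 11.8 ± 2.88 to 38.5 ± 9.58 CPM, while the quinone reductase gene Nqo1 fell by 1.94 ± 0.35. With the replicate block 10 were lower, and without sham 1 to 3 and cut 1 to 3 in turn 1, 1, 2, 2, 4 and 5 were higher and 2, 1, 1, 1, 2 and 11 lower. With the muscle covariate 2 were higher and 1 lower. Of 20 glycolysis genes, 3 were higher and 3 lower (3 and 3 adjusted over the list alone; median -0.41; limma camera, adjusted p = 0.304, and called only without cut 3, at -1.27). The enolase gene Eno1 rose by 1.30 ± 0.21, from 110 ± 2.58 to 270 ± 71.8 CPM, the phosphoglycerate mutase gene Pgam1 rose by 1.12 ± 0.27, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.04 ± 0.27. Pgam1 was not called without sham 1 to 3 or cut 1 (0.97 to 1.22) and Pdk1 without any library but cut 3 (-1.09 to -0.85). Glycolysis medians were -1.40, -1.13 and 0.40 in cut 1 to 3, with muscle shares of 1.63%, 0.531% and 15.8%. On leaving out sham 1 to 3 and cut 1 to 3 in turn, 1, 1, 1, 1, 2 and 6 members were higher and 0, 0, 0, 0, 0 and 13 lower, and 1 was higher with the muscle covariate.

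Of 21 immediate early and stress genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone; median 0.25; limma camera, adjusted p = 0.83). The nuclear receptor gene Nr4a2 rose by log2 2.37 ± 0.36, from 19.9 ± 7.03 to 103 ± 35.7 CPM, and the heat shock gene Hspa1a fell by 1.85 ± 0.28. Without sham 1 to 3 and cut 1 to 3 in turn, 3, 1, 2, 2, 3 and 6 of these genes were higher, and 1 with the muscle covariate. Of 13 skin genes, only Sbsn was higher (none adjusted over the list alone in edgeR's test, where 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom none; median 0.15; limma camera, adjusted p = 0.573). Sbsn rose by 1.77 ± 0.52, was called otherwise only without cut 3 among the libraries left out (1.19 to 1.86 without the rest). It shares exon sequence with a gene on the same strand, and was not called on FPKM (1.14 and 1.47). The desmosome gene Dsp stood at -1.25 ± 0.57. Without cut 3, 3 skin genes were lower, Dsp (-2.08) among them. Of 10 erythroid genes, 2 were lower (5 adjusted over the list alone; median -1.39; limma camera, adjusted p = 0.0336; adjusted p = 0.612 with an estimated correlation; not called without sham 3, at -1.01, or cut 1, at -1.25). Slc4a1, the band 3 anion exchanger of red cells, fell by 1.72 ± 0.48, from 1.82 ± 0.678 to 0.548 ± 0.284 CPM. In this list 7 members were lower with the replicate block and 6 in DESeq2. Without sham 1 to 3 and cut 1 to 3 in turn 2, 0, 1, 1, 1 and 8 were lower. None was lower with the muscle covariate, and the per-library medians were -1.45, -1.74 and -0.65, nearest to sham in cut 3, where the muscle share was near sham too. Slc4a1 was not called without sham 1 to 3 or cut 2 (-1.90 to -1.39).

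**Figure D4:**
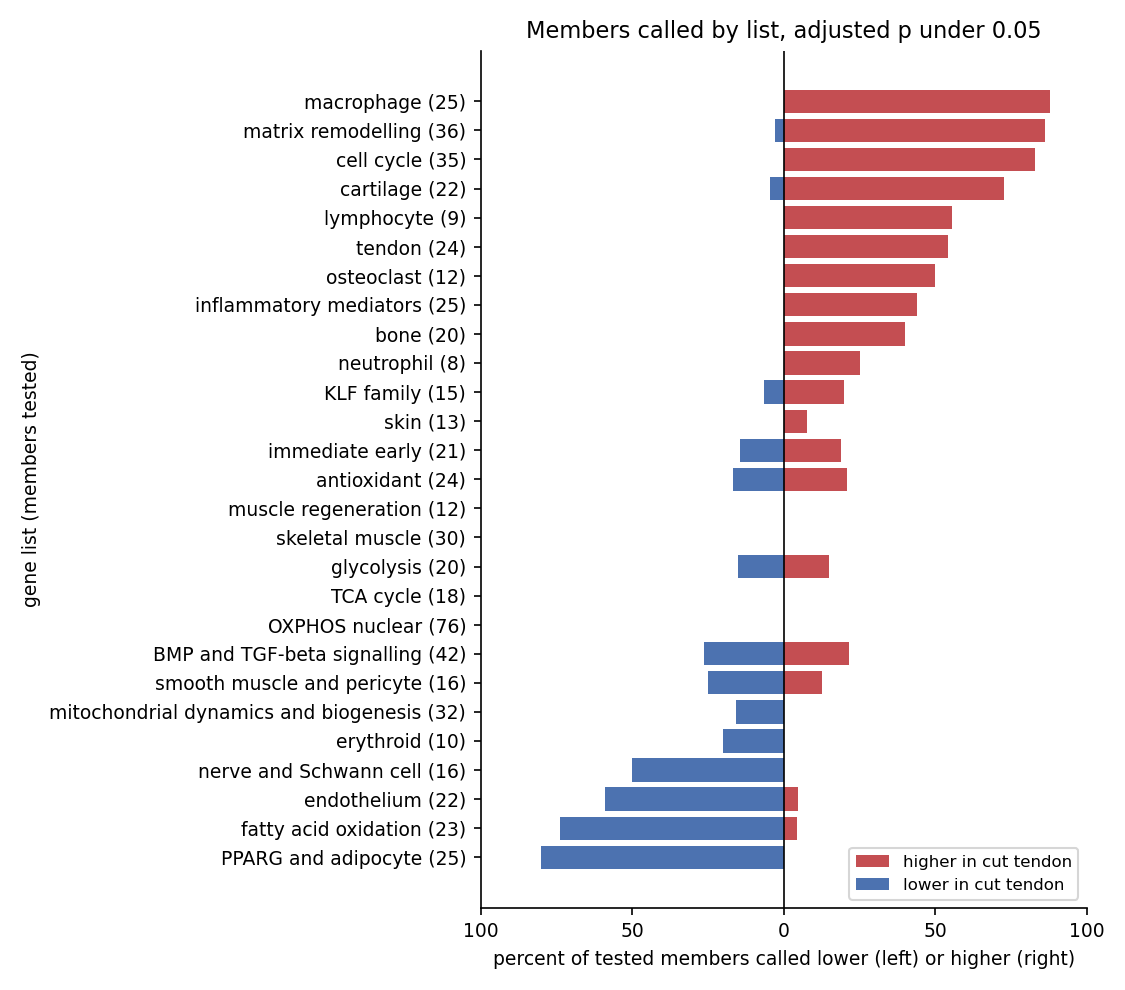
Bars show the percent of tested members of 27 gene lists called lower (blue, left) or higher (red, right) in cut tendon at an adjusted p under 0.05, with the number tested in parentheses. Macrophage (22 of 25), matrix remodelling (31 of 36) and cell cycle (29 of 35) genes were mostly higher, PPARG and adipocyte (20 of 25) and fatty acid oxidation (17 of 23) genes mostly lower, and OXPHOS, TCA cycle, skeletal muscle and muscle regeneration genes were not called in edgeR's quasi-likelihood test, though DESeq2 called 31, 12, 9 and 0 of them lower.

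Across the 27 lists with tested genes, camera with its preset correlation called 17 and with an estimated correlation none (smallest adjusted p = 0.369). The preset test also called between 7 and 19 lists in the other ways of splitting the 6 libraries 3 against 3. Of the 104 genes selected for naming, 85 were called, and 59 of those were also called without each library in turn. With the replicate block, lower members numbered 2 in the KLF family, matrix, tendon and neutrophil lists and 1 in the bone, osteoclast and inflammatory mediator lists. In the main fit, the shares of higher members in the KLF family (3 of 15), antioxidant (5 of 24) and immediate early (4 of 21) lists were near that of all tested genes (2968 of 14561).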

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

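The alternative with the muscle covariate was chosen only after the result was seen, and the others were planned. Over 18 settings, the direction and side of the threshold were kept in most cases: for the 102 genes selected besides Klf2 and Pparg, 1051 values kept both, 38 passed only under the alternative, 28 no longer passed and 4 reversed, and with a library left out the numbers were 512, 16, 82 and 2. Pparg kept its call throughout. With the replicate block, 3161 genes were higher and 2522 lower, and besides the calls and counts given in the report and that of Cox6a2 (-3.16), the block changed no other call of a selected gene or of a list as a whole, and moved no other count in a list by over 1.5 times. The cause was not tested for any change below. Fewer libraries give less power in general, but without cut 3 more genes were called (4212 higher and 4392 lower, against 2968 and 1789 with all libraries).

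With the muscle covariate 1483 genes were higher and 633 lower, and Klf2 (0.22) was not called. Neither were Lep, Nnat, Polrmt, Etfa, Klf16, Pgam1, Pdk1, Tnfsf11, Lmod1, Mcam, Cspg4, Cdh19, Drp2, Sbsn, Slc4a1, Ptgs2 and Scx, while Myl2 (-0.92) and Mb (-0.90) were. Medians of lists no longer called were OXPHOS -0.14, TCA cycle -0.26, mitochondrial dynamics -0.20, osteoclast 0.43, Schwann cell -0.73 and erythroid -0.67. Signs reversed for KLF family -0.0425, glycolysis 0.47, bone -0.00693, BMP and TGF-beta -0.035, skeletal muscle 0.21, muscle regeneration 0.71 (called higher), immediate early -0.42, Cdh15 0.28, Cox6a1 -0.0198, Cox7a2 0.10 and Cox8a -0.0926. The covariate was made from the skeletal muscle list, so the values of that list, Myl2 and Mb under it are circular. This holds in part for glycolysis, which shares Eno3 and Pgam2 with that list. At least 2-fold changes numbered 1813 higher and 1006 lower, and DESeq2 called 2776 lower. Klf2 was not called with no filter (0.87), on FPKM (0.83 and 0.85) or without muscle and erythroid genes in the library sizes (0.86). With no filter, the neutrophil (-0.115) and muscle regeneration (0.0169) medians reversed.

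With an estimated correlation camera called none of the lists it had called, at unchanged medians: OXPHOS -1.02, TCA cycle -1.19, mitochondrial dynamics -0.70, fatty acid oxidation -1.66, adipocyte -1.94, cartilage 5.34, osteoclast 0.71, tendon 1.76, matrix 2.62, macrophage 1.79, lymphocyte 1.45, inflammatory 1.32, endothelium -0.62, skeletal muscle -1.55, Schwann cell -1.19, cell cycle 2.15 and erythroid -1.39. With each library left out in turn, higher genes ranged from 1091 to 4212 and lower genes from 436 to 4392, and Klf2 from 0.63 to 1.11. Ranges of other results that changed were Cox8a -0.10 to 0.14, glycolysis -1.27 to -0.14, bone 0.77 to 1.48, BMP and TGF-beta -0.00489 to 0.12, smooth muscle -0.64 to -0.38, muscle regeneration -2.71 to -0.0301, Schwann cell -1.41 to -0.80, erythroid -1.70 to -1.01 and immediate early -0.0562 to 0.52. Depth limits genes near a single count (0.0319 to 0.0418 CPM), such as Il6 in sham.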

Other observations

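The gene groups in this part and the tests of the adipocyte, endothelium, cell cycle and other cell type lists were chosen only after the result was seen, and the split tests before. The isoform and muscle covariate tests were chosen after the muscle shares of the libraries were seen, and before their own values were. KEGG terms carried by the deposited annotation were tested with Fisher's test on 301 terms, with Benjamini-Hochberg adjustment over 602 tests. Genes were taken as independent although they are not. Of these tests 71 passed at an adjusted p under 0.05, and only a few of the terms are given here. Lysosome genes were higher in 63 of 114 cases (Fisher's test, adjusted p = 1.1e-11). Ctsh, a lysosomal cysteine protease, rose by log2 1.64 ± 0.13, from 27.1 ± 1.28 to 84.6 ± 9.03 CPM, and the group was higher beside a macrophage list with 22 of 25 genes higher (median 1.79). Histone cluster genes, expressed as DNA is copied, were higher in 38 of 50 cases (median 2.17), and Hist1h1b, a linker histone gene, rose by 3.23 ± 0.27. Near-identical histone copies may share reads, so single genes of this group are uncertain. The group as a whole was not tested, and its count stood beside a cell cycle median of 2.15. With sham 1 to 3 and cut 1 to 3 left out in turn, 40, 33, 39, 46, 53 and 80 lysosome genes were higher. The histone counts were then 27, 26, 28, 29, 32 and 38. With the muscle covariate 43 lysosome and 27 histone genes were higher.

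In the N-glycan term 23 of 46 genes were higher (Fisher's test, adjusted p = 0.00125), and Mgat2, a glycosyltransferase of the Golgi, rose by log2 1.35 ± 0.19. In the chondroitin and dermatan sulfate synthesis term 12 of 19 were higher (Fisher's test, adjusted p = 0.00379), and Chsy1, a chondroitin synthase, rose by 3.08 ± 0.41, from 23 ± 3.23 to 194 ± 94 CPM. With sham 1 to 3 and cut 1 to 3 left out in turn, the counts were 11, 9, 11, 13, 14 and 30 for N-glycans and 8, 6, 6, 9, 10 and 15 for chondroitin sulfate, and with the muscle covariate 11 and 8. Genes of valine, leucine and isoleucine degradation were lower in 24 of 47 cases (Fisher's test, adjusted p = 6.2e-08). Bckdhb, a subunit of the branched-chain dehydrogenase, fell by 1.15 ± 0.14. With each library left out in the same order, 5, 3, 4, 5, 6 and 37 were lower, 35 with the replicate block and 5 with the muscle covariate. Of 28 transcription factor families none passed (Fisher's test, lowest adjusted p = 0.434, for ETS factors, 8 of 22 higher).

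The lower mitochondrial lists may reflect less skeletal muscle RNA in cut 1 and 2. In 4 pairs of isoforms, the log2 fold change of the muscle form minus that of the widely expressed form had a median of -1.77. The differences were -2.43 for Cox6a2 against Cox6a1, -1.19 for Cox7a1 against Cox7a2, -1.68 for Cox8b against Cox8a and -1.86 for Slc25a4 against Slc25a5. Less muscle RNA predicts such differences, although none of the 8 genes was called in edgeR's test on all 6 libraries. Cox6a2, Cox7a1 and Cox8b belong to the skeletal muscle list, whose lower share in cut 1 and 2 was seen before the pairs were chosen. Their fall therefore restates the muscle loss and does not by itself show why the OXPHOS list was lower. The widely expressed forms stood at 0.44 (Cox6a1), -0.62 (Cox7a2), 0.03 (Cox8a) and 0.40 (Slc25a5). Cox6a2 was called with the replicate block (-3.16), and without cut 3 all but Cox8a and Slc25a5 were called, Cox6a1 as higher (0.60) and the others as lower. Lower OXPHOS expression beyond the muscle loss could not be told: with the muscle covariate the list median was -0.14, above -0.25, which met the prediction for no such change, written before this value was computed. The list mean was -0.13 ± 0.384 (SE, 3 residual degrees of freedom), too wide to exclude such a change, and this error was added after the median was seen. The adjusted value also rests largely on cut 3, where the OXPHOS median was -0.13.

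A smaller muscle share could raise every other cell type alike, and with it the macrophage, matrix, cartilage and cell cycle lists. The endothelium, Schwann cell and adipocyte lists, 3 of 3 compared, were instead called lower by camera with its preset correlation. They were chosen for this after they were seen to be lower. A smaller muscle share as a cause is not excluded by this, since vessels, nerves and fat within muscle could be lost with it. None of the 3 calls held with an estimated correlation, and that of Schwann cells was also lost without sham 1, without cut 3 and with the muscle covariate. The endothelium and adipocyte calls held under these last 3 settings, and 13 of 22 and 20 of 25 single genes were lower. More uninjured tendon in the dissected piece was argued against as the only cause by the cell cycle median of 2.15, since resting tissue holds few dividing cells. Injury itself and another difference in the dissected tissue were not tested and stay open.

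The lower Pparg value could come from fewer adipocytes, since the adipocyte list had a median of -1.94 beside -1.70 for Pparg. The list may not measure adipocytes alone, since it shares Acsl1 with the fatty acid oxidation list. With the muscle covariate 13 members were lower in place of 20. Lower Pparg per adipocyte could not be told: Pparg minus the list median was 0.24, and many list members are themselves PPARγ targets. The endothelium list gave no sign of more endothelial cells behind the higher Klf2: its median was -0.62, with 13 of 22 genes lower and 1 higher. Its call was lost with an estimated correlation (limma camera, adjusted p = 0.538), and the list was seen to be lower before this question was put. A list median also cannot exclude a shift among endothelial cells that differ in Klf2. No other source of Klf2, such as immune cells, was tested.

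The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 4757 genes and the highest other 0, so 1 of 10 splits reached the real value. The 3 other splits that part the 3 same-numbered pairs each called 0 genes and mix the 2 groups. For lists, the real split called 17 and the highest other 19, and 6 of 10 splits called at least as many as the real split.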
